A study of Mus musculus with 9 samples.

How the data were processed

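RNA was extracted with TRIzol and made into libraries with an Illumina TruSeq kit, per the labels' protocols. The submitters' processing notes name Bowtie, TopHat, Cufflinks and the mm9 build. Their versions, their settings and the release of the annotation are not given in the sources used here. The deposited accessions are RefSeq ones. All cells had been starved of serum and given 10 µM phycocyanobilin, the chromophore that OptoSOS needs, per the labels' protocols.

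The deposited table has 1 line per transcript and no header line. The annotation columns that the authors deposited beside the values give a locus, a gene symbol with a RefSeq accession, and a class code that relates the transcript to the reference. These belong to no sample and were the only columns used. The 12 columns of values, 3 more than the 9 samples, were not used. Their names, running numbers written inside the cells, matched no sample's labels. Matching the columns by their order or by their values would have been a guess. The tests planned for the groups (limma on log values, a rule of fold changes and tests of gene lists) were therefore not run, and the depth per sample was not determined.

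Transcripts, loci and symbols were counted with Python 3.11.15. A gene's transcripts are the different accessions under its symbol. Gene lists were matched by symbol, with older symbols where the list gave them. Coordinates are not given, since the only genome annotation at hand was of another build than mm9. It was not used for any count.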

Results

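The study measured polyadenylated RNA in mouse NIH3T3 fibroblasts carrying OptoSOS, a light-controlled switch that recruits the catalytic part of the Ras activator SOS2 to the plasma membrane. By the sample labels, 3 libraries came from unstimulated cells. PDGF, a growth factor that signals through receptor tyrosine kinases, was given at 100 ng/mL, with 1 library each at 30, 60 and 120 min. Light-stimulated cells were sampled at the same times after stimulation, again with 1 library each. The design asks which genes change after the growth factor, which change after activation of Ras by light, and how the responses differ. The 12 columns of values in the deposited table are named only by a running number inside their cells. No label of the 9 samples gives this number, so none of the design's comparisons was made. No expression level, fold change, spread between replicates or depth is therefore reported, and what follows describes only which genes the table lists and with how many transcripts.

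The table listed 30273 transcripts at 23183 loci, under 23205 gene symbols. These transcripts were counted as lines, whereas the transcripts of a gene were counted as different accessions. Whether an accession stood on several lines was not counted. Of these transcripts, 26796 had a RefSeq accession of a protein-coding mRNA and 3477 had one of a non-coding RNA. The class code of 30228 transcripts was the one for a complete match to the reference transcript, and that of the other 45 was the one for a transcript contained in it. There were 4246 genes with 2 or more transcripts, and 189 symbols stood at 2 or more loci. A locus here is a locus identifier in the table, and its position in the genome was not read.

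Of 398 genes in 22 lists fixed before the data were examined, 389 had a transcript, and 20 lists had one for every member. Being listed means only that the table holds the symbol with a RefSeq accession. It does not show that the cells expressed the gene, since 22 of 23 markers of other cell types were listed as well. All 26 immediate early genes were listed. Fos, Egr1 and Junb, transcription factors known to be induced within minutes of mitogen addition, each had 1 transcript, whereas Myc, Arc and Nr4a2 had 2 each. All 17 genes in the list for negative feedback on the ERK pathway were listed with a single transcript. Among them were the ERK phosphatase gene Dusp6 and the Sprouty gene Spry4. For these 17 genes the symbol stood for 1 accession, but how many lines of the table each gene had was not counted. A single accession was not particular to this list. The 12 mRNA decay and antiproliferative regulators had 1 each, as did the 7 matched members of the mitochondrial and histone list. Over all 23205 symbols, 4246 had 2 or more.

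Other lists held genes with many transcripts. These are counts of accessions under a symbol, and no value was read. They therefore do not show which genes or transcripts the cells expressed. Crem, which encodes activators and repressors of cAMP-responsive transcription, had 16 transcripts. The actin-binding tropomyosin gene Tpm1 had 10, the matrix gene Fn1 had 7, and the angiogenic growth factor gene Vegfa and the hyaluronan receptor gene Cd44 had 6 each. Of 20 genes for Ras and PDGF signalling, all were listed. The PDGF receptor genes Pdgfra and Pdgfrb had 2 transcripts each, Hras1 had 3, and Sos1 and Sos2 had 1 each. Hmgcs1, which encodes an enzyme of cholesterol synthesis, had 2 transcripts under 2 locus identifiers. Whether these are different places in the genome was not checked. In the list of mitochondrially encoded and replication-dependent histone genes, 7 of 15 members had a transcript. All 7 were histone genes, and no mitochondrially encoded member was matched by symbol. In the list of markers of other cell types, 22 of 23 members had a transcript. The members without a match were not analysed here.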

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

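The alternatives planned before the data were examined concern expression values and were not run, because no column of values was matched to a sample. For the same reason no replicate was left out. The settings that follow were chosen after seeing the data. Keeping only transcripts with a complete match to the reference left out 45 of 30273, so it could change little. It gave 23205 genes, 4246 genes with 2 or more transcripts and 389 list members, the same counts as with all transcripts. Keeping only protein-coding accessions gave 20448 genes, 3881 genes with 2 or more transcripts and 389 list members. The lists name protein-coding genes, so this setting could hardly lower the 389.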
